A study of Mus musculus with 6 samples.

How the data were processed

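Aortas of 6-month-old mice, labelled as lacking apolipoprotein E, were profiled by bulk RNA sequencing after 28 days of angiotensin II from an implanted osmotic pump. Per the labels' protocols, RNA was extracted with TRI Reagent, messenger RNA was selected on poly-T beads, and cDNA was primed with random hexamers. The groups were 3 wild-type littermates (WT) and 3 littermates lacking soluble ST2 (sST2-KO), and samples were assigned from their titles. The authors deposited raw counts per Ensembl gene, not normalized, in 1 table for all 6 libraries. Genome build mm39 is named in the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here. Gene symbols, biotypes and coordinates were taken from the deposited table. Reads of overlapping or antisense genes and of near-identical gene copies cannot be told apart at this level, and 882 rows repeat a symbol; where a listed symbol had several identifiers the more abundant was used.

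Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM, and sST2-KO was compared with WT by glmQLFit and glmQLFTest with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-normalized CPM (counts scaled to a common library size), given as mean ± SD over n = 3 libraries per group. The standard error (SE) of a log2 change is its size divided by the square root of the F statistic. Positive log2 changes are higher in sST2-KO. Before the data were examined, 54 gene lists for aortic disease, cell types and RNA quality were fixed, and 827 of their 829 entries were found in the table. The 50 lists with at least 5 tested genes were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01). Camera with an estimated correlation and the fry test were run beside it. Adjusted p-values of lists are over the 50 lists. A list's median has its SE over member genes, which are not independent.

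The rule for naming genes was also fixed in advance. It takes Il1rl1, Il33 and Il1rap, then genes past the threshold. Where none pass, it takes the 6 named protein-coding genes per direction with the lowest unadjusted p. Genes with Gm, Rik, pseudogene or similar placeholder symbols do not count as named. It adds up to 4 members with the lowest p of each list described and up to 2 abundant members of a cell type list. Genes named outside this rule are said to be chosen after their values were seen. Genes near Il1rl1 were compared with other genes by Fisher's exact test, two-sided, in a window of 5 Mb on each side.

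The tests were tried on simulated counts for the comparison of sST2-KO with WT, drawn for 16377 genes from the observed means, library sizes and dispersions, with 200 genes changed in each of 5 runs. At the observed dispersion, 2.81% of genes changed 2-fold and 75.6% of genes changed 8-fold were recovered at the threshold, and 31 of 436 calls were false. With dispersions divided by 10 the recovered shares were 78.96% and 97.8%, and 92 of 1073 calls were false. A list lowered by a log2 change of -1.5 was called in 5 of 5 runs, with the preset and with the estimated correlation. Genes were drawn independently, so this does not show recovery of lists whose genes vary together, as those here do.

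Totals were 15615658 to 17988552 counts per library, so 3 counts correspond to 0.148 to 0.239 CPM, the level that a count of 0 allows. Shares of counts have exact Clopper-Pearson intervals at the 95% level. Intervals and floors cover counting error only. No pair of libraries agreed within sampling noise: over genes with at least 50 counts in a pair, the median squared difference was 5.86 to 50.2 times that of counting noise. Every column of values was matched to a sample. Genes were called peculiar to a library where log2 of CPM plus 1 lay more than 2 above every other library.

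Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, other low-count filters, protein-coding genes alone, a threshold of 0.1, a test against a 1.5-fold change, a replicate block, and leaving out each library. Alternatives added after seeing the data left out WT replicate 3 and sST2-KO replicate 2 together, genes peculiar to a library, or mitochondrially encoded genes. GC content was taken from the longest GENCODE vM21 transcript of each gene, matched by identifier for 16164 of the tested genes; no coordinate of that annotation was used. Plots were drawn with matplotlib 3.10.9.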

Results

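The series asks how loss of soluble ST2, the secreted isoform encoded by Il1rl1 that binds the cytokine IL-33, affects the aorta in a mouse model of angiotensin II-induced aortic disease. Counts per gene were given for 3 WT and 3 sST2-KO aortas, all labelled as Apoe-deficient. Apoe itself was looked up after the main results were seen. It had 15.1, 11.6 and 507 CPM in WT replicates 1 to 3 and 172, 86.7 and 145 CPM in sST2-KO replicates 1 to 3. The WT library with 507 CPM also held liver transcripts, as described below. Total counts were 16740787, 16088057 and 16163727 in WT replicates 1 to 3 and 17988552, 17785126 and 15615658 in sST2-KO replicates 1 to 3. Of 56748 genes in the table, 30169 had a count and 16377 were tested.

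Il1rl1 (ENSMUSG00000026069, chromosome 1, 40468730 to 40504575, mm39) was low in every library. It reached 2.81, 9.49 and 4.35 CPM in WT replicates 1 to 3 and 2.39, 2.82 and 4.86 CPM in sST2-KO replicates 1 to 3, from 42 to 119 counts. The group means were 5.55 ± 3.50 and 3.35 ± 1.32 CPM (SD, n = 3 each), a log2 change of -0.72 (SE 0.54) that did not pass (edgeR quasi-likelihood test, adjusted p = 0.594). Without WT replicate 2 the log2 change was -0.11. Counts per gene add the soluble and the membrane isoform, so these values check the genotype labels only weakly. Il33, which encodes the ligand of ST2, had 170 ± 43.1 CPM in WT and 63.8 ± 25.9 CPM in sST2-KO (SD, n = 3 each) with no overlap between the groups. Its log2 change was -1.42 (SE 0.33), short of the threshold in edgeR (adjusted p = 0.354) and past it in DESeq2 (adjusted p = 0.0108). Il1rap, the co-receptor, had a log2 change of -0.54 (SE 0.35, edgeR adjusted p = 0.559). The IL-33 and ST2 pathway list had a median of -0.21 over 15 tested genes and was not called (camera adjusted p = 0.0724; adjusted p = 0.510 with an estimated correlation). Its member with the lowest p after Il33, the eosinophil attractant Ccl11, had 23.9 ± 5.09 CPM in WT and 13.8 ± 1.54 CPM in sST2-KO (SD, n = 3 each). Without sST2-KO replicate 2 the list's median was -0.30 (camera adjusted p = 0.0235; adjusted p = 0.561 with an estimated correlation).

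No single gene passed the threshold in either direction. The edgeR quasi-likelihood test called 0 genes higher and 0 lower in sST2-KO, with a lowest adjusted p of 0.264. At an unadjusted p under 0.05 there were 832 higher and 974 lower genes, against 819 in all by chance. The groups did not overlap for 1488 genes higher and 1644 genes lower, 19.1% of those tested, where chance gives 10%. DESeq2 called 59 higher and 172 lower genes, limma-voom called 0 and 0, and limma-voom with sample quality weights called 8 and 35. Ranks by p given next are among named protein-coding genes, which leaves out Gm, Rik and pseudogene symbols. The lower genes with the lowest unadjusted p were the interferon-inducible Ifi207 (log2 change -1.38, SE 0.14) and Ifi204 (-1.74, SE 0.22), the chemokines Ccl9 (-1.29, SE 0.15) and Cxcl2 (-3.14, SE 0.42), Ms4a6d (-1.45, SE 0.19) and Rab7b (-1.07, SE 0.14). Ifi207 had 68.3 ± 4.36 CPM in WT and 26.2 ± 1.04 CPM in sST2-KO, and Ccl9 had 152 ± 12.6 and 62.1 ± 4.14 CPM (SD, n = 3 each). The higher genes with the lowest p were the galactosyltransferase B3galt2 (2.03, SE 0.29), Gtf2ird1 (1.19, SE 0.20), the inositol phosphate kinase Itpk1 (1.13, SE 0.20), the ion exchanger Slc24a3 (0.82, SE 0.15), the receptor kinase Grk3 (1.497, SE 0.28) and the fatty acid receptor Ffar4 (2.72, SE 0.51). Adjusted p-values of these 12 genes were 0.264 to 0.335 in edgeR, and all 12 separated the groups without overlap. DESeq2 called all 12 and limma-voom with quality weights 11. The 12 were picked by their p in these same counts, so neither the separation nor these calls is independent support. Outside the naming rule, 2 genes are given after their values were seen. Gm48207 had 1, 0 and 0 counts in WT replicates 1 to 3 and 64, 71 and 95 in sST2-KO replicates 1 to 3 (edgeR unadjusted p = 5.05e-05, adjusted p = 0.264). Gm45844 had 2, 0 and 0 counts and 65, 25 and 40 (edgeR unadjusted p = 0.000805, adjusted p = 0.335). DESeq2 and limma-voom with quality weights called both.

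**Figure D1:**
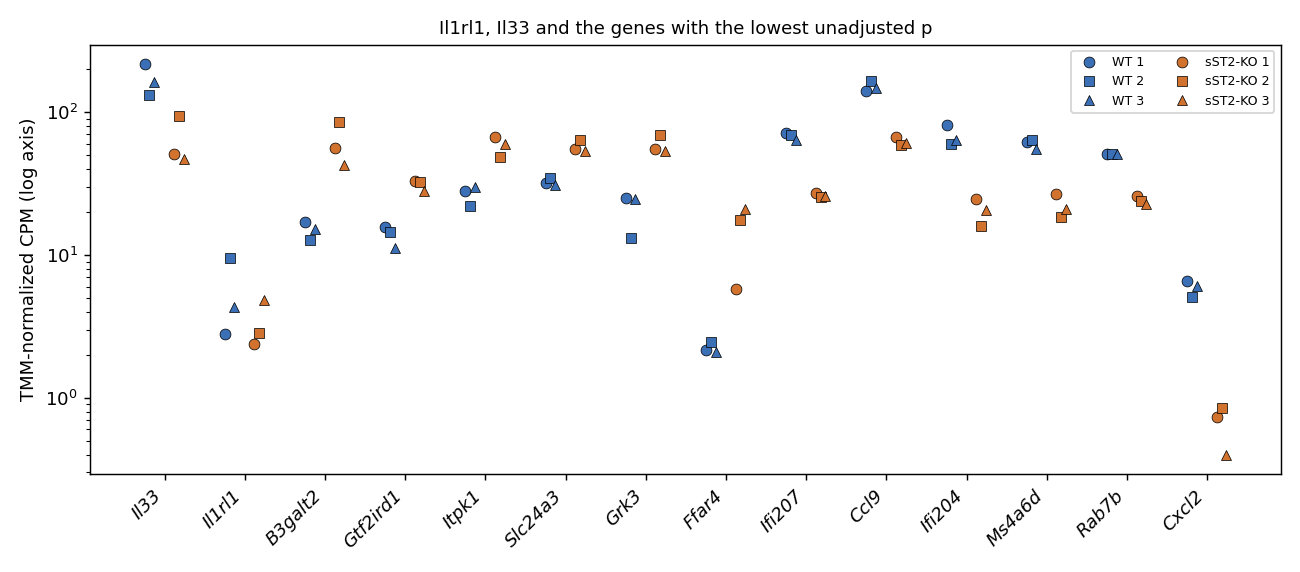
TMM-normalized CPM on a log axis of Il33, Il1rl1 and the 12 genes with the lowest unadjusted p, with 1 point per library (blue WT, orange sST2-KO; circle, square and triangle for replicates 1, 2 and 3). The groups overlap for Il1rl1 and not for the other genes, and none of them passed the adjusted threshold in edgeR, while DESeq2 called Il33 and the 12. The 12 were picked by p from these same counts, which favours genes without overlap.

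Libraries differed in ways that the groups do not give. The library of sST2-KO replicate 2 held transcripts of airway epithelium: Scgb1a1, the club cell secretory protein, had 12598 CPM there and at most 7.89 CPM elsewhere, and Epcam had 128 CPM against at most 0.662 CPM. Genes peculiar to this library numbered 918 and took 13.5% of its counts (95% exact interval 13.45 to 13.48). The library of WT replicate 3 held liver transcripts: Alb, the serum albumin gene, had 6205 CPM there and at most 3.83 CPM elsewhere, and Apoa1 had 719 CPM against at most 1.28 CPM. Genes peculiar to it numbered 193 and took 2.53% of its counts (95% exact interval 2.52 to 2.53). Mitochondrially encoded genes took 37.8% of counts in WT replicate 2 and 7.08% in sST2-KO replicate 2, against 18.4 to 23.7% in the other 4 libraries. The main axis of a principal component analysis, 38.2% of the variance, set sST2-KO replicate 2 apart from the rest, and the next, 27.4%, set WT replicate 2 apart.

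**Figure D2:**
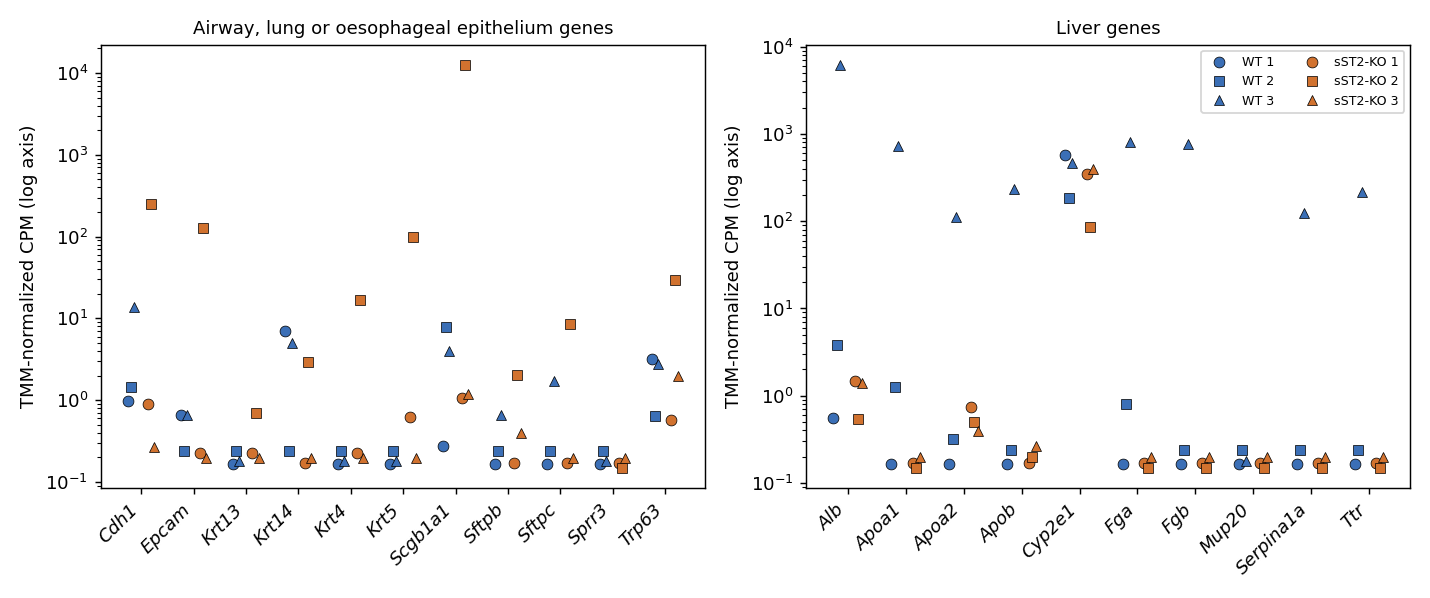
TMM-normalized CPM on a log axis of the listed airway, lung or oesophageal epithelium genes (left) and liver genes (right), with 1 point per library; values under the floor of 3 counts are drawn at that floor. Scgb1a1 is at 12598 CPM in sST2-KO replicate 2 and Alb at 6205 CPM in WT replicate 3.

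Gene lists were lower in sST2-KO more often than higher. With the preset correlation, camera called 23 of 50 lists lower and 5 higher. With an estimated correlation it called 0, with a lowest adjusted p of 0.397, and the directional fry test also called 0, with a lowest adjusted p of 0.0683 for the platelet list. The fry test for change in either direction called 7 lists. The calls below therefore rest on the preset correlation of 0.01, while the median estimated correlation in the called lists was 0.364. Splits of the libraries that do not follow genotype gave 9 to 29 called lists with this preset, as described further below. Counts of genes that passed when adjusted over a list alone ignore the other lists and the choice of list. They are descriptive, and their genes vary together. Further lists called lower were those of alternatively activated macrophages, foam cells, inflammatory cytokines, the inflammasome, the cell cycle, protease inhibitors, and elastic fibres with collagen crosslinking. Of these, the foam cell and protease inhibitor lists were not called without sST2-KO replicate 2 (camera adjusted p = 0.508 and 0.234). The cell cycle list was not called without WT replicate 3 (camera adjusted p = 0.186).

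Genes of macrophages and of leukocyte recruitment were lower in sST2-KO. In the macrophage and monocyte list 17 of 18 tested genes had negative log2 changes, with a median of -1.07 (camera adjusted p = 1.30e-11; adjusted p = 0.397 with an estimated correlation). Of these genes 14 passed in edgeR when adjusted over the list alone and 0 over all genes tested, where DESeq2 called 6, with Adgre1, Itgam and Plek among them. Adgre1, which encodes the macrophage marker F4/80, had 91.5 ± 2.64 CPM in WT and 32.2 ± 9.07 CPM in sST2-KO, and the integrin gene Itgam had 47.0 ± 5.63 and 18.6 ± 3.53 CPM (SD, n = 3 each). Plek had 142 ± 8.28 and 51.1 ± 13.9 CPM, while Lyz2, the most abundant member, had 1925 ± 105 and 2192 ± 898 CPM (SD, n = 3 each), with 3152 CPM in the library with airway transcripts. In the chemokine list 20 of 21 genes had negative log2 changes, with a median of -1.39 (camera adjusted p = 1.82e-12; adjusted p = 0.397 with an estimated correlation), and 12 passed when adjusted over the list alone. Ccl6 had 292 ± 23.0 CPM in WT and 123 ± 19.8 CPM in sST2-KO (SD, n = 3 each). Without sST2-KO replicate 2 the macrophage median was -1.001 and the chemokine median -1.21.

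The type I interferon, complement and antigen presentation lists were also lower. All 20 tested interferon response genes had negative log2 changes, with a median of -1.13 (camera adjusted p = 3.07e-09; adjusted p = 0.430 with an estimated correlation), and 12 passed when adjusted over the list alone. The RNA sensor Ddx58 had 57.4 ± 5.84 CPM in WT and 30.3 ± 3.67 CPM in sST2-KO, and Ifit2 had 45.3 ± 14.3 and 18.7 ± 2.23 CPM (SD, n = 3 each). Oasl1 had a log2 change of -1.74 (SE 0.35). The median over the list of log2 CPM minus the gene's mean was -0.29 in WT replicate 2 and -0.34 in sST2-KO replicate 2. It was 1.13 and 0.74 in WT replicates 1 and 3. The groups did not overlap for 9 of the 20 genes. The list's median log2 change was -0.87 without WT replicate 1 and -1.44 without WT replicate 2. The complement list had a median of -0.67 over 15 genes (camera adjusted p = 3.28e-07; adjusted p = 0.397 with an estimated correlation), with the anaphylatoxin receptor C3ar1 at -1.51 (SE 0.29) and the protease gene C1s1 at -0.88 (SE 0.20). The MHC class II list had a median of -0.73 over 9 genes (camera adjusted p = 2.82e-05; adjusted p = 0.430 with an estimated correlation), with H2-DMb1 at -0.83 (SE 0.24) and H2-Ob at -1.31 (SE 0.42). Adjusted over the list alone in edgeR, 2 complement genes and 0 MHC class II genes passed. By the measure per library given for interferon genes, complement was at -0.075 in WT replicate 2 and -0.15 in sST2-KO replicate 1.

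Lists of platelets, B cells, neutrophils and erythroid cells were called lower. The mast cell list had a median of 0.36 and was not called (camera adjusted p = 0.193). The plasma cell list had a median of 0.035 and was not called (camera adjusted p = 0.521). Without sST2-KO replicate 2 the plasma cell median was -0.55 (camera adjusted p = 0.0467; adjusted p = 0.652 with an estimated correlation), and without both that library and WT replicate 3 it was -0.54 (adjusted p = 0.0799). The T cell and NK cell list had a median of -0.038 (camera adjusted p = 0.0311; adjusted p = 0.633 with an estimated correlation), and it varied with the library left out. It was 0.38 without sST2-KO replicate 2 (adjusted p = 0.623), -1.10 without sST2-KO replicate 1 (camera adjusted p = 7.01e-07; adjusted p = 0.359 with an estimated correlation) and -0.23 without WT replicate 2 (camera adjusted p = 0.00348; adjusted p = 0.619 with an estimated correlation). Without sST2-KO replicate 3 it was 0.092 (camera adjusted p = 0.0323, in the lower direction; adjusted p = 0.727 with an estimated correlation), and with a replicate block it was -0.41 (camera adjusted p = 0.00546; adjusted p = 0.539 with an estimated correlation). The list was not called without WT replicate 1 (adjusted p = 0.207) or WT replicate 3 (adjusted p = 0.0679). The platelet and megakaryocyte list had a median of -1.66 over 10 genes (camera adjusted p = 4.10e-09; adjusted p = 0.397 with an estimated correlation), and 8 passed when adjusted over the list alone. Ppbp had 26.5 ± 6.47 CPM in WT and 4.96 ± 1.80 CPM in sST2-KO, Gp9 had 4.31 ± 1.52 and 0.797 ± 0.177 CPM, and the abundant Pf4 had 42.6 ± 9.18 and 26.7 ± 6.04 CPM (SD, n = 3 each). Itgb3 had a log2 change of -0.31 (SE 0.32). The B cell list had a median of -1.02 over 12 genes (camera adjusted p = 0.000123; adjusted p = 0.430 with an estimated correlation), with Ms4a1 at -1.42 (SE 0.49) and Cd22 at -0.57 (SE 0.62); without both WT replicate 3 and sST2-KO replicate 2 the median was -0.54. The neutrophil list had 8 of 9 negative log2 changes and a median of -1.09 (camera adjusted p = 0.00188; adjusted p = 0.430 with an estimated correlation), and without sST2-KO replicate 3 it was -1.14 (adjusted p = 0.0619). Without both WT replicate 3 and sST2-KO replicate 2 it was -0.52 (camera adjusted p = 0.0339; adjusted p = 0.743 with an estimated correlation). Lcn2 was at -1.46 (SE 0.51). The 1 positive member, Ltf, also a product of airway glands, had 2074 CPM in sST2-KO replicate 2 and at most 22.4 CPM elsewhere; its log2 change was -2.11 without that library. All 8 tested erythroid genes had negative log2 changes, with a median of -2.86 (camera adjusted p = 0.000433; adjusted p = 0.476 with an estimated correlation), and 0 passed in edgeR when adjusted over the list alone. Without both libraries the erythroid median was -1.57 (adjusted p = 0.107). By the measure per library given for interferon genes, the erythroid list was at 2.25, -0.36 and 2.54 in WT replicates 1 to 3. It was at 0.29, -3.84 and -0.70 in sST2-KO replicates 1 to 3. sST2-KO replicate 1 also lay above WT replicate 2 in the B cell list (0.29 against 0.0097) and the neutrophil list (0.10 against -0.48). The platelet list separated the groups by this measure. What differs between these libraries was not tested.

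Genes of the extracellular matrix were lower as a group. The collagen list had 14 of 19 negative log2 changes and a median of -0.60 (camera adjusted p = 5.54e-06; adjusted p = 0.430 with an estimated correlation), and 4 passed when adjusted over the list alone. Col3a1, a main fibrillar collagen of arteries, had 3911 ± 245 CPM in WT and 1761 ± 421 CPM in sST2-KO, and Col8a1 had 175 ± 16.2 and 84.1 ± 30.8 CPM (SD, n = 3 each). Col11a1 had a log2 change of -1.67 (SE 0.44). The proteoglycan and matricellular list had a median of -0.75 over 21 genes (camera adjusted p = 2.18e-06; adjusted p = 0.430 with an estimated correlation), and 3 passed when adjusted over the list alone. Without WT replicate 2 the median was -0.40. Lum had 1403 ± 173 CPM in WT and 492 ± 117 CPM in sST2-KO, Spp1, which encodes osteopontin, had 1935 ± 167 and 632 ± 239 CPM, and Fmod had 252 ± 59.5 and 95.7 ± 39.4 CPM (SD, n = 3 each). The matrix protease list had a median of -0.50 over 20 genes (camera adjusted p = 2.99e-05; adjusted p = 0.430 with an estimated correlation), and 0 passed in edgeR when adjusted over the list alone. Without sST2-KO replicate 1 the median was -0.83. Mmp12, the macrophage elastase, was at -1.28 (SE 0.32), Mmp19 at -1.03 (SE 0.22) and Mmp2 at -0.76 (SE 0.22). The adventitial fibroblast list had 13 of 16 negative log2 changes and a median of -0.50 (camera adjusted p = 0.000398, and 0.430 with an estimated correlation). By the measure per library, collagens were at 0.050, 0.48 and 0.25 in WT replicates 1 to 3. They were at -0.024, -0.48 and -0.49 in sST2-KO replicates 1 to 3. The elastic fibre and crosslinking list was at -0.023, 0.42 and 0.14 in WT and -0.024, -0.52 and 0.0053 in sST2-KO, so the groups overlapped there.

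Lists of oxidative metabolism, glycolysis and brown fat were higher in sST2-KO, with large differences between libraries. All 22 nuclear-encoded oxidative phosphorylation genes had positive log2 changes, with a median of 0.71 (camera adjusted p = 6.52e-05; adjusted p = 0.592 with an estimated correlation); Uqcrc1 was at 0.96 (SE 0.41) and Sdhc at 0.66 (SE 0.29). Without WT replicate 2 the median was 0.46 (camera adjusted p = 0.0274; adjusted p = 0.811 with an estimated correlation), and without sST2-KO replicate 3 it was 0.42 (camera adjusted p = 0.0223; adjusted p = 0.738 with an estimated correlation). All 13 mitochondrially encoded genes had negative log2 changes, with a median of -0.68 (camera adjusted p = 0.00854; adjusted p = 0.628 with an estimated correlation). That median was -0.23 (adjusted p = 0.692) without sST2-KO replicate 2 and -0.0083 (adjusted p = 0.417) without WT replicate 2. It was -1.16 without sST2-KO replicate 1 (camera adjusted p = 0.000562; adjusted p = 0.591 with an estimated correlation), and the list also stayed called without WT replicate 1, WT replicate 3 or sST2-KO replicate 3. The fatty acid oxidation list had a median of 0.94 over 19 genes (camera adjusted p = 0.000797; adjusted p = 0.592 with an estimated correlation), and without WT replicate 2 it was 0.65 (adjusted p = 0.0835). Ech1 had 111 ± 38.7 CPM in WT and 248 ± 114 CPM in sST2-KO (SD, n = 3 each). Ppargc1a had 5.02, 2.71 and 3.88 CPM in WT replicates 1 to 3 and 7.61, 11.8 and 56.3 CPM in sST2-KO replicates 1 to 3. The brown adipocyte list had a median of 1.72 over 14 genes (camera adjusted p = 0.000684; adjusted p = 0.523 with an estimated correlation), and without sST2-KO replicate 3 it was 1.11 (adjusted p = 0.0986). In none of the oxidative phosphorylation, fatty acid oxidation and brown adipocyte lists did a gene pass in edgeR when adjusted over the list alone. Without both WT replicate 3 and sST2-KO replicate 2 their medians were 1.14, 1.48 and 2.42 (adjusted p = 0.727 for each in camera with an estimated correlation). Ucp1, the uncoupling protein of brown fat, had 44.7, 2.87 and 32.3 CPM in WT replicates 1 to 3 and 591, 35.0 and 1433 CPM in sST2-KO replicates 1 to 3. Cidea had 126, 5.50 and 87.9 CPM and 351, 36.2 and 429 CPM in the same order. The hypoxia and glycolysis list had 17 of 18 positive log2 changes and a median of 0.41 (camera adjusted p = 0.00239; adjusted p = 0.476 with an estimated correlation), and without sST2-KO replicate 3 it was 0.24 (adjusted p = 0.0857). The white adipocyte list had 16 of 18 positive log2 changes and a median of 0.54, and was not called (camera adjusted p = 0.246). Without sST2-KO replicate 2 its median was 0.995 (camera adjusted p = 6.19e-05; adjusted p = 0.614 with an estimated correlation), and without WT replicate 1 it was 0.96 (camera adjusted p = 0.0405; adjusted p = 0.787 with an estimated correlation). Without both WT replicate 3 and sST2-KO replicate 2 it was 1.11 (camera adjusted p = 1.21e-05; adjusted p = 0.727 with an estimated correlation). With a replicate block it was 0.44 (camera adjusted p = 0.00137; adjusted p = 0.481 with an estimated correlation). It was 0.13 without WT replicate 2 (adjusted p = 0.675), 0.13 without sST2-KO replicate 1 (adjusted p = 0.994) and 0.16 without sST2-KO replicate 3 (adjusted p = 0.869).

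Smooth muscle and endothelial lists were not called. The contractile smooth muscle list had a median of 0.24 over 20 genes (camera adjusted p = 0.0915; adjusted p = 0.658 with an estimated correlation), with Actg2 at 1.28 (SE 0.40) and Des at 2.16 (SE 0.84). Des had 391 CPM in sST2-KO replicate 2 and at most 54.7 CPM elsewhere. Without WT replicate 2 the list's median was 0.69 (camera adjusted p = 0.000146; adjusted p = 0.486 with an estimated correlation), and without sST2-KO replicate 1 it was 0.33 (camera adjusted p = 0.0413; adjusted p = 0.670 with an estimated correlation). Without sST2-KO replicate 3 it was 0.035 (adjusted p = 0.472), and without WT replicate 1 it was 0.070 (adjusted p = 0.771). The endothelial list had a median of 0.34 over 16 genes (camera adjusted p = 0.118; adjusted p = 0.797 with an estimated correlation), with Cldn5 at 1.23 (SE 0.46), Egfl7 at 0.82 (SE 0.41), Pecam1 at 0.43 (SE 0.35) and Vwf at 0.27 (SE 0.32). Without sST2-KO replicate 2 its median was 0.67 (camera adjusted p = 3.52e-08; adjusted p = 0.561 with an estimated correlation), and without sST2-KO replicate 1 it was -0.017 (adjusted p = 0.846). With a replicate block it was 0.24 (camera adjusted p = 0.0424; adjusted p = 0.722 with an estimated correlation).

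**Figure D3:**
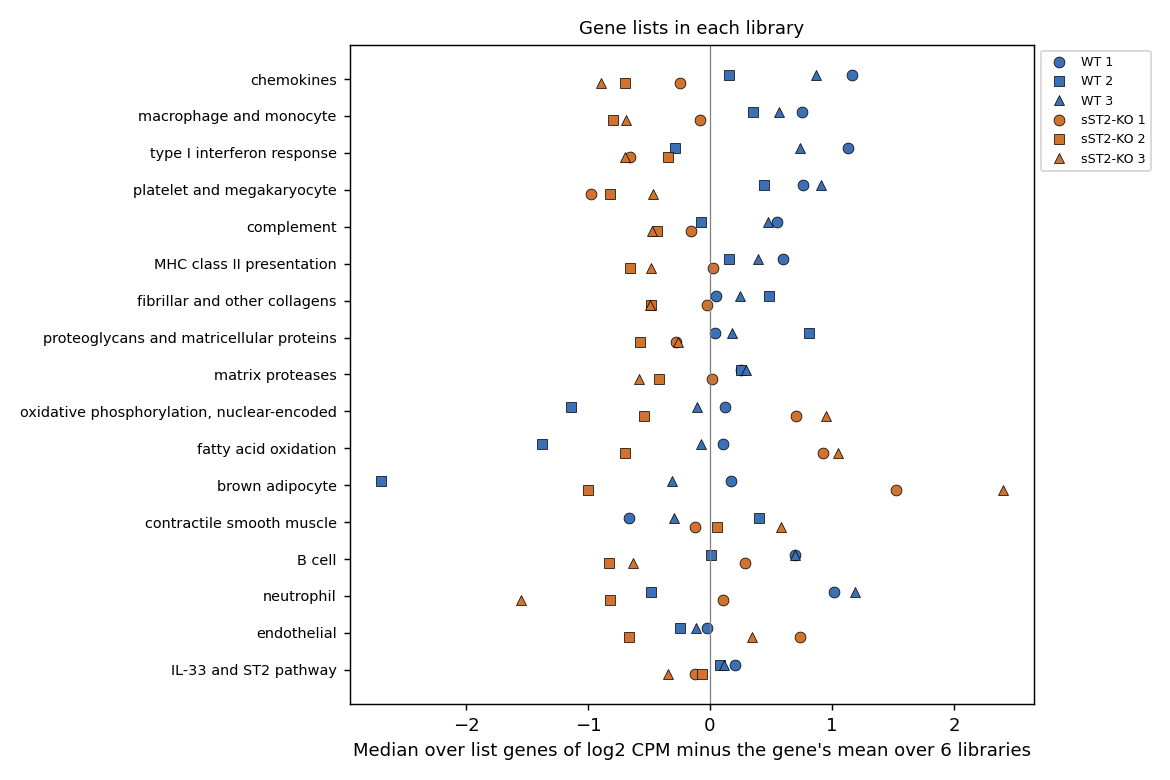
For each described gene list, the median over its genes of log2 CPM minus the gene's mean over the 6 libraries, with 1 point per library (blue WT, orange sST2-KO; circle, square and triangle for replicates 1, 2 and 3). In the macrophage list WT libraries lie between 0.36 and 0.75 and sST2-KO libraries between -0.79 and -0.08, whereas in the brown adipocyte list sST2-KO replicate 2, at -1.004, lies below WT replicates 1 and 3.

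Genes near Il1rl1 were examined because a targeted allele can carry flanking DNA. Of 70 tested genes within 5 Mb, edgeR called 0; with 0 calls among all genes, this count says nothing about position. At an unadjusted p under 0.05 there were 12, 17.1%, against 1794 of 16307 other genes (odds ratio 1.67, two-sided Fisher's exact test p = 0.122). Col3a1 lies in this window.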

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

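The test of other airway genes and that of other liver genes were written down before those genes were looked at; both tests of genotype and the choice of Clca1 and Fgb as examples came after the values were seen. Counts of genes outside the comparison, because they failed the low-count filter, drew attention in 2 libraries. They took 4.44% of counts in sST2-KO replicate 2 (95% exact interval 4.43 to 4.45) and 1.23% in WT replicate 3 (1.227 to 1.237), against 0.116 to 0.199% in the other 4. Clca1, a goblet cell gene, had 99521 counts in sST2-KO replicate 2 and at most 1 count elsewhere. Fgb, which encodes fibrinogen beta, had 12791 counts in WT replicate 3 and at most 3 counts elsewhere.

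For sST2-KO replicate 2, RNA of airway tissue in the library is a candidate explanation. Of 12 ciliated-cell genes chosen before they were looked at, 10 were more than 4-fold above every other library with 1 CPM added to each value, Foxj1 among them at 336 CPM. Without this offset, a setting chosen after seeing the data, all 12 were. An effect of the genotype runs against the other sST2-KO libraries: both exceeded every WT library in 1 of 11 airway genes. Whether tissue was taken along at dissection or RNA was mixed later stays open.

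For WT replicate 3, RNA of liver in the library is a candidate explanation. Of 12 hepatocyte genes chosen before they were looked at, 10 were more than 4-fold above every other library with the same offset and 11 without it, such as Serpinc1 at 105 CPM. Hepatocyte-like expression in wild-type aortas runs against the other WT libraries, which both exceeded every sST2-KO library in 1 of 10 liver genes. The genes Afp and H19, abundant in fetal liver and chosen after their values were seen, had 1631 and 865 CPM in this library and at most 0.455 and 18.8 CPM elsewhere. Igf2, looked up with them, was far lower, at 8.59 CPM in this library and at most 0.797 CPM elsewhere. The source of this RNA stays open.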

How the results depend on the processing

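Settings that left out both WT replicate 3 and sST2-KO replicate 2, genes peculiar to a library, mitochondrially encoded genes, or the offset in marker counts were chosen after seeing the data; the others were fixed in advance. Counts of genes past the threshold stayed at 0 higher and 0 lower in edgeR with RLE or upper-quartile scaling, either other filter, protein-coding genes, a threshold of 0.1, the 1.5-fold test and the 3 added settings, and in limma-voom. DESeq2 called 59 higher and 172 lower, and quality weights gave 8 and 35; the cause was not tested. DESeq2 gave no adjusted p for 14793 of 30169 genes. Of the 43 quality-weighted calls, 42 were among its calls, which came from the same counts. Sample weights were 1.89, 0.27 and 5.78 in WT replicates 1 to 3 and 1.46, 0.30 and 0.77 in sST2-KO replicates 1 to 3. The highest weight went to the library with liver transcripts. Upper-quartile scaling moved the genes at an unadjusted p under 0.05 from 832 higher and 974 lower to 669 and 1107. Leaving out each replicate gave 0 genes higher and 0 to 1 lower; the 1 is Gm45104, without sST2-KO replicate 2, named after its value was seen. It gave 3 to 8 lists higher (3 without sST2-KO replicate 3, 8 without sST2-KO replicate 1) and 20 to 27 lower. Camera with an estimated correlation and fry each gave 0 higher and 0 lower lists. Without both doubted libraries 7 and 18 lists were called, 21 of them among the 28 reported and in the same direction.

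The labels do not give a pairing of samples by replicate number. Libraries with equal replicate numbers carry different numbers in their library names. Results with a replicate block therefore rest on a pairing that the labels do not state. Deviations from group means correlated at 0.15, 0.05 and -0.09 across genes for equal numbers, and at -0.12 to 0.045 for unequal numbers across groups. Yet 4 of 6 libraries correlated best with their own number in the other group. With the replicate block 0 genes were higher and 0 lower, and 6 lists higher and 24 lower.

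The log2 change of Il1rl1 ranged from -1.09 to -0.11 when replicates were left out and stayed short of the threshold. Of the genes near Il1rl1, 12 counted at an unadjusted p. The 6 values for single genes that changed sign were of Lyz2 (-0.016 with quality weights, -0.17 to 0.43 when replicates were left out, negative without sST2-KO replicate 2, and -0.19 without both doubted libraries), Ltf (-0.87 with quality weights, -2.11 without sST2-KO replicate 2 to 9.81 without WT replicate 3) and Vwf (-0.062 without sST2-KO replicate 1 to 0.46 without WT replicate 1). The endothelial median was -0.017 without sST2-KO replicate 1 to 0.67 without sST2-KO replicate 2. Of 1000 values for named genes under alternatives, 944 kept direction and side of the threshold and 50 passed it, with DESeq2 or quality weights. Of 255 medians of a part of the lists described, 216 kept both, 31 lost the call and 7 gained it. Lists outside this count include some whose calls changed with the libraries used. Among them are the T cell, plasma cell, white adipocyte, erythroid, hypoxia, mitochondrially encoded, Schwann cell and osteogenic lists. The foam cell, protease inhibitor and cell cycle lists each lost the call when some library was left out. The TGF-beta, renin-angiotensin, dendritic cell and lymphatic endothelial lists each gained one. With 3 libraries a group and a biological coefficient of variation of 0.419, spread between libraries limits single genes.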

Other observations

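Tests in this part were chosen after the results were seen, except the test of GC content on the macrophage list, which was written down before its result. The endochondral and osteogenic list had a median of -0.47 over 16 genes (camera adjusted p = 0.00854; adjusted p = 0.397 with an estimated correlation), and its adjusted p was 0.0503 without WT replicate 3 and 0.178 without WT replicate 2, where the median was -0.22. Col2a1, the main collagen of cartilage, had 29.6, 126 and 67.1 CPM in WT replicates 1 to 3 and 3.12, 12.4 and 2.59 CPM in sST2-KO replicates 1 to 3. Ibsp, which encodes bone sialoprotein, had 8.99, 12.1 and 8.77 CPM and 0.284, 0.990 and 2.13 CPM. Both genes were named after their values were seen, and neither passed in edgeR (adjusted p = 0.339 for each), while DESeq2 called both. Of other cartilage genes looked up after Col2a1, Hapln1 had 2.92, 13.3 and 4.59 CPM in WT replicates 1 to 3 and 1.31, 3.41 and 2.06 CPM in sST2-KO replicates 1 to 3. Col9a1, Col9a2, Col9a3, Matn1, Matn3 and Snorc had at most 6.33 CPM in any library and no direction is read from them. The Schwann cell and neuron list had a median of 1.62 over 11 genes (camera adjusted p = 0.0422, and 0.592 with an estimated correlation). Without sST2-KO replicate 2 it was 0.31 (camera adjusted p = 0.406). The list was also not called without WT replicate 1 (median 1.63, camera adjusted p = 0.0526) or WT replicate 3 (median 1.66, camera adjusted p = 0.0616).

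Clock genes set 1 library apart. In sST2-KO replicate 1, Arntl had 22.6 CPM against 3.03 to 6.73 CPM in the other 5 libraries, and Per2 had 15.7 CPM against 87.8 to 135 CPM. Hspb1 had 565 CPM in sST2-KO replicate 3 and at most 140 CPM elsewhere. These genes were also named after their values were seen.

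Lower macrophage genes in sST2-KO were weighed against 3 technical explanations. Airway tissue that dilutes the aortic RNA of sST2-KO replicate 2 would need the median to shrink without that library, but it was -1.001 (SE 0.15 over genes) against -1.07 with all. Added fat or other tissue that dilutes every aortic cell type alike runs against the contractile list. Its median lay 1.31 (SE 0.23 over genes, which vary together) above that of the macrophage list. This covers only added tissue that brings few contractile genes of its own, which was not tested. Des, a contractile list member, had 391 CPM in sST2-KO replicate 2 and at most 54.7 CPM elsewhere. Without that library the contractile median was 0.39. GC content bias between libraries runs against the median relative to genes of like GC content, -1.11 (SE 0.14). Fewer macrophages, lower expression per macrophage and chance were not told apart here. A difference between the groups around Apoe, described below, was not separated from the sST2 genotype either.

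Chance in the assignment of libraries to groups could not be assessed to 0.05, because 6 libraries allow 10 splits into 3 and 3. The real split gave 0 genes past the threshold and the highest other split gave 0, so 10 of 10 gave as many. With 0 in the real split this outcome was fixed, so the gene count says nothing about chance. With the preset correlation, the real split gave 28 gene lists. The other splits gave 25, 10, 10, 27, 23, 19, 9, 10 and 29, so 2 of 10 gave as many. The number of lists called with that setting therefore does not set the genotype split apart. With an estimated correlation every split gave 0. At an unadjusted p under 0.05 the real split gave 1806 genes and the highest other split 1305. The split with 29 lists set WT replicate 1, sST2-KO replicate 2 and sST2-KO replicate 3 against the rest.

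Log2 changes rose with GC content across genes (Spearman's rho = 0.33; genes are not independent replicates). The median was -0.24 in the lowest and 0.34 in the highest of 10 classes of GC content. Among libraries the deviation from the gene mean ran most against GC content in WT replicate 2 (rho = -0.39). All 28 called lists kept their direction and more than 50% of their median relative to genes of like GC content.

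Apoe counts differed between libraries that share the Apoe-deficient label: 15.1, 11.6 and 507 CPM in WT replicates 1 to 3 and 172, 86.7 and 145 CPM in sST2-KO replicates 1 to 3. The 507 CPM are from the library with liver transcripts, where Alb had 6205 CPM. Outside that library, every sST2-KO value lay above both WT values. Over all libraries the log2 change was -0.40 (SE 1.31, edgeR adjusted p = 0.911). A hypothesis is that a chromosome segment around Apoe differs between the groups. Of 104 tested genes within 5 Mb of Apoe (chromosome 7, 19430034 to 19433113), 29 had an unadjusted p under 0.05, 27.9% against 10.9% of other genes (odds ratio 3.15, Fisher's exact test p = 1.64e-06), and within classes of GC content the odds ratio was 2.70. As high a share was reached by 0.724% of 12012 overlapping windows around other genes. Of the 29 genes, 28 were higher in sST2-KO. The exception, Gm45104, had 14.3, 14.9 and 13.5 CPM in WT replicates 1 to 3 and 0.284, 1.78 and 0.466 CPM in sST2-KO replicates 1 to 3.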
